A study of Homo sapiens with 12 samples.

How the data were processed

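Total RNA was sequenced from CAL-1 cells, a human line derived from a plasmacytoid dendritic cell (pDC) leukemia. Cells were rested for 6 h in 0.1% FBS and then kept for 12 h without treatment (mock), with IFN-β at 1000 U/mL, with R848 at 1 µg/mL, or with R848 and B18R, each at 1 µg/mL. R848 is a small agonist of the endosomal receptors TLR7 and TLR8, and B18R is a vaccinia virus protein that binds type I interferon and keeps it from its receptor. Each of the 4 groups had 3 libraries, made after ribosomal RNA removal with a strand-specific kit and read as paired ends. The libraries were sequenced in 3 runs named in the library names. Run 1 held no library with B18R, run 2 held none with IFN-β, and run 3 held a library of each of the 4 groups. Per the labels, RNA was treated with DNase during extraction.

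The labels contradict each other on treatment. Sample titles and treatment tags call the R848 libraries IFN lambda and the R848 plus B18R libraries IFN-β with R848 and B18R, and a second cell line tag names PH5CH8, a hepatocyte line. Groups were taken from the library names and the series design, which give mock, IFN-β, R848 and R848 plus B18R in CAL-1 cells. A CpG-B treatment mentioned in the protocol has no group here.

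The authors deposited a single table of log2 values, log2 CPM (counts scaled to library size) with an offset of 0.5 counts, for each gene and library. Per the labels, FastQC 0.11.3, cutadapt 1.8.3, STAR 2.4.0, HTSeq and limma were used with the genome build GRCh37, without an order or the settings for strand and multi-mapped reads. The table had 18440 rows. Of its identifiers, 6 were repeated with identical values, which left 18434 genes. Inverting the offset gave whole numbers for 100% of values under 200 counts, within 0.02, and recovered totals of 46274627 to 74521171 counts per library. The recovered counts of every listed gene summed to at least 51 over the libraries, so genes below that level are not in the table. The values are relative to scaled library sizes, with factors from 0.876 to 1.16 of each total. Symbols were found for 95.0% of the identifiers and gene classes, from GENCODE release 29, for 95.6%. The other 815 identifiers stayed unclassified. That release is on another genome build than the counts, so no coordinates are given.

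Genes with a log2 value of at least 0 (1 CPM) in at least 3 libraries were tested, 12801 in all, of which 1070 were lncRNAs and 10570 protein-coding. The 12 libraries were fitted with limma 3.58.1 in R 4.3.3, a mean per group, empirical Bayes moderation with an intensity trend and two-sided tests. Adjusted p-values are Benjamini-Hochberg values over all genes tested in a comparison, and a gene was called at an adjusted p under 0.05. Each ± beside a log2 change is the moderated standard error, n = 3 libraries per group. Since the replicates are all of a single cell line, p-values of single genes measure the spread among these libraries, which includes technical spread. Comparisons were IFN-β, R848 and R848 plus B18R against mock, R848 plus B18R against R848, and R848 against IFN-β.

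Gene lists, 23 in all, were fixed from general knowledge before the data were examined: interferon-stimulated genes (ISGs), interferon receptor and JAK-STAT signalling, interferon genes, NF-κB targets, cytokines and chemokines, dendritic cell maturation, MHC class I, MHC class II, pDC identity, Toll-like receptor (TLR) pathway, cell cycle, ribosome biogenesis and MYC targets, cholesterol, ER stress, glycolysis, cell death regulators, known lncRNAs, markers of hepatocytes, T and NK cells, B cells, and monocytes with conventional dendritic cells, mitochondrially encoded genes, and structured RNAs without a poly(A) tail. Of the 584 entries over all lists, 445 were found in the table. The list of hepatocyte markers also held general epithelial markers. An entry whose identifier in the table had no symbol could not be found. The 19 lists with at least 5 tested genes were compared with all other genes by camera in limma at a preset correlation of 0.01, adjusted over the lists. With that preset, a camera p-value rests mainly on the spread of statistics over genes, not on the spread among libraries. Very small values are therefore not to be read as certainty over libraries. For the ISGs with IFN-β, the camera adjusted p was 6.5e-121 with the preset and 1.4e-07 with an estimated correlation. Of the 51 list results called over the 5 comparisons, 32 kept an adjusted p under 0.05 with an estimated correlation, and the others are given with that p. Where a list result is given with genes called one way only, limma called none the other way. There were 40 such results, with 20 genes in all, and at most 4 in a list, at an unadjusted p under 0.05 the other way. Genes to be named were fixed by a rule written before the data were examined: per comparison, the 12 largest increases and 8 largest decreases among called genes whose 3 libraries all lay above or below the other 3 and whose higher group was at or above the lower quartile of level (2.57 log2 CPM), the 8 and 4 largest for lncRNAs, and any member of the fixed lists. Protein-coding genes with no symbol were passed over for the next with a symbol. A fold against a group with 0 counts uses a floor of 3 counts over the group and is a lower bound, and with 1 to 3 counts the count ratio is given with its 95% interval, which covers counting error only. These intervals treat counts as independent. In every library small even counts outnumbered small odd counts (1050 against 677 genes in the first mock library), so the intervals may be too narrow. For other genes with a group level near that of 3 counts in a library, the size of a change depends on the offset and is approximate.

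The retained share of an R848 response is the change with R848 plus B18R against mock divided by the change with R848 against mock, both as log2, for genes raised at least 2-fold by R848. Figures and matching used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The procedure was tested on simulated libraries of 12801 genes with known changes: in IFN-β against mock it recovered 19 of 66 genes changed by 0.5 log2 units, 55 of 67 changed by 1 and 64 of 67 changed by 2, and 17 of 20 genes of a list raised by 1. Of 165 calls in all, 10 were of unchanged genes. In simulated R848 against mock with no change put in, limma called 0 genes, with 666 at an unadjusted p under 0.05.

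Alternatives chosen before the data were examined were no filter and a stricter filter (log2 value of 2), quantile normalization, median centring, no intensity trend, array weights, the 2 groups of a comparison alone, replicate number as a block, sequencing run as a factor, an adjusted p under 0.01, a 2-fold minimum, adjustment over lncRNAs alone, a retained share under 0.5, an estimated correlation or fry for the lists, and leaving out each library. Precision weights on the recovered counts, scaling by each library's recovered total and leaving out both libraries of low mitochondrial share were chosen after seeing the data. Alternatives foreseen for count tables and for linear values (other size factors, other pseudocounts) were not run, since the deposited values are on a log scale.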

Results

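The series asked which long noncoding RNAs (lncRNAs) respond to TLR7 signalling and to type I interferon in activated plasmacytoid dendritic cells, the cells that make most type I interferon in a viral infection. Steady-state RNA was counted in 12 libraries of CAL-1 cells, 3 each of mock, IFN-β, R848 and R848 plus B18R, after 12 h. The recovered totals per library were 46274627 to 74521171 counts. The level of a gene is given as the authors' log2 CPM.

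The first principal component of the 12801 tested genes held 57.8% of the variance and the second 20.8%. Libraries lay together by group, with the first R848 plus B18R library farthest from its group, at a root mean square distance of 0.585 log2 units from the other two against 0.196 to 0.398 for the other libraries. The share of counts on mitochondrially encoded protein genes was 0.717% in the second mock library and 0.403% in the first R848 plus B18R library, against 1.55% to 2.63% in the others.

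**Figure D1:**
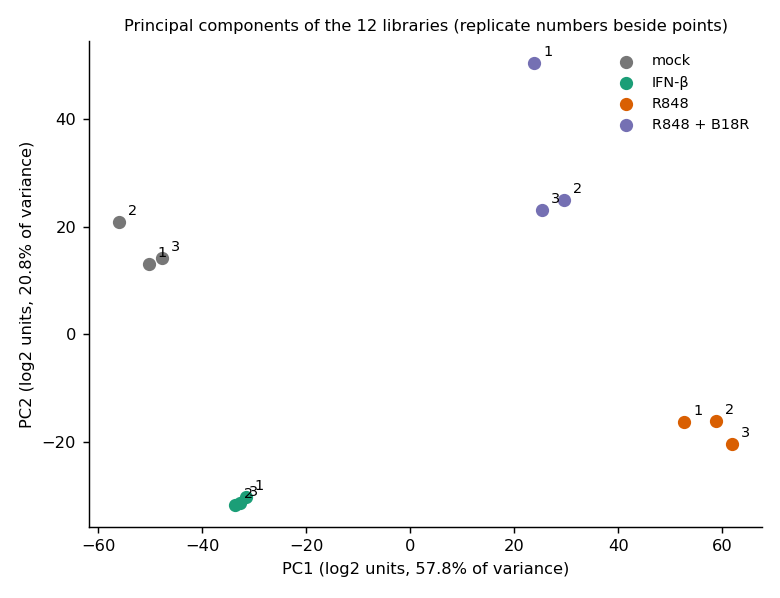
Scores of the 12 libraries on the first and second principal components of the tested genes (log2 CPM), coloured by group. The first component, 57.8% of the variance, parted the 6 libraries with R848 from the 6 without.

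The comparison of IFN-β with mock asked which genes type I interferon changed on its own. IFN-β raised the antiviral effectors of the interferon response. These included OAS1 and OAS2, which sense double-stranded RNA and activate RNase L, their relative OASL, IFIT1, which binds viral RNA caps, and MX2 and IFI6, which block virus replication. The signalling genes STAT2 and IRF9 rose with them, as did TLR7, its adaptor MYD88 and the interferon regulator IRF7. TNFSF13B (BAFF), TNFSF10 (TRAIL) and the peptide transporter TAP1 rose, whereas the inflammatory cytokine IL1B and the lysozyme gene LYZ fell. All 38 tested ISGs were higher, before and after adjustment over the list alone.

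OAS1 (ENSG00000089127) rose by 8.60 ± 0.12 log2 units (adjusted p = 3.0e-14) and IFIT1 (ENSG00000185745) by 8.48 ± 0.24 (adjusted p = 2.8e-11), in 3 of 3 libraries each. MX2 rose by 10.78, IFI6 by 10.29, OAS2 by 10.05, EPSTI1 by 9.18, IFI44 by 8.98, XAF1 by 8.37, IFI27 by 7.12, LGALS3BP by 5.87 and OASL by 5.77. In mock MX2 was at −4.816 (SD 2.525) and IFI44 at −5.282 (SD 1.768), below the value of 3 counts in a mock library (−4.262 to −4.074). The mock SD of LGALS3BP was 2.082. The size and order of these changes are therefore approximate. IFI44L had 2 counts over the mock group and 11114 with IFN-β, a ratio of 6172 (95% interval 1708 to 50968). IRF9 rose by 2.73, IRF7 by 1.88, TLR7 by 1.75, STAT2 by 1.72 and MYD88 by 1.58. IL1B fell by 0.93 ± 0.09 (adjusted p = 1.0e-05), in 3 of 3 libraries. The change was −0.97 for MB, −0.92 for LYZ, −0.81 for SPNS2 and for MICAL2 and −0.80 for GRIN2B. RASGRP2 fell by 0.82, a call that ended without the second mock library or the first or the second IFN-β library (adjusted p 0.0518 to 0.0569). MDFI fell by 1.13, but its call ended without any single library of the 6 (adjusted p 0.0629 to 0.154).

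In all, 481 genes were higher and 91 lower, 223 and 11 of them by at least 2-fold. The lower count was 38, 60 and 49 without the first, the second and the third mock library and 42, 28 and 32 without the first, the second and the third IFN-β library. The other libraries enter this comparison by the shared spread alone, and there were 58 lower without the second R848 library and 771 higher and 294 lower without the first R848 plus B18R library. Without both libraries of low mitochondrial share 739 were higher and 367 lower, and with array weights 1209 and 1121. The lower count was 161 with quantile normalization, 179 with scaling by library total, 201 with the 2 groups alone and 52 with replicate number as a block. Higher genes were 84.1% of the calls, 74.8% with quantile normalization, 69.7% with scaling by library total, 72.4% without the first R848 plus B18R library, 66.8% without both libraries of low mitochondrial share and 51.9% with array weights. In 3464 genes the 3 IFN-β and 3 mock libraries did not overlap, against 10% of genes by chance. The ISGs had a median log2 change of 4.30 (camera adjusted p = 6.5e-121). In the JAK-STAT list 7 of 20 genes were higher (10 adjusted over the list alone, camera adjusted p = 1.2e-09). MHC class I genes moved upward, with 11 of 21 higher (14 over the list alone, median 0.64, camera adjusted p = 2.5e-16, and 0.0447 with an estimated correlation). Cell death regulators (4 of 21 higher, 7 over the list alone) had a camera adjusted p of 0.000205, and of 0.0726 with an estimated correlation. NF-κB targets, cytokines, dendritic cell maturation genes, MHC class II genes, pDC identity genes and the TLR pathway were not called as lists with IFN-β (camera adjusted p 0.236, 0.16, 0.136, 0.948, 0.16 and 0.0648). Of those lists, 2 of 26, 2 of 15, 2 of 14, 1 of 15, 2 of 27 and 3 of 19 genes were higher (6, 4, 4, 1, 5 and 3 adjusted over the list alone), and 1 NF-κB target, 1 cytokine and 1 pDC identity gene were lower (3, 1 and 1, and 1 maturation gene, over the list alone). CD274, at 2.52, was among the higher genes, as was HLA-DOB at 0.88, a call that ended without the first or the third mock library, the second or the third IFN-β library or the second R848 library (adjusted p 0.0573 to 0.183). The direction of the NF-κB, cytokine and MHC class II lists is not given, since it turned with the scaling or lay near 0.

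Among lncRNAs, IFN-β raised antisense transcripts such as IRF1-AS1, named for the interferon regulator IRF1, PSMB8-AS1, named for a subunit of the immunoproteasome, L3MBTL2-AS1 and USP30-AS1. LUCAT1, a stress-induced lncRNA, and CHROMR rose too. L3MBTL2-AS1 (ENSG00000235513) rose by 1.57 ± 0.18 (adjusted p = 7.1e-05) and IRF1-AS1 (ENSG00000197536) by 1.35 ± 0.14 (adjusted p = 1.7e-05), in 3 of 3 libraries each. RUSC1-AS1 rose by 1.38, NRSN2-AS1 by 1.37, AP1G2-AS1 by 1.34, CHROMR by 1.23 and HOXB-AS1 by 1.16. TRMT61A-DT rose by 1.06, a call that ended without the first mock library or the second or the third IFN-β library (adjusted p 0.0503 to 0.0606). From the fixed list of known lncRNAs, USP30-AS1 rose by 2.10, LUCAT1 by 1.53 and PSMB8-AS1 by 0.72. That list had 4 of 33 genes higher, also over the list alone (camera adjusted p = 0.385). Of 1070 lncRNAs tested, 32 were higher and 5 lower. Their total of 37 was 22 without the first mock library and 24 and 21 without the first and the third IFN-β library, and 57 without the first R848 plus B18R library. Among the lower ones, WAKMAR2 fell by 0.66, a call that ended without the first or second mock library or the first or the third IFN-β library (adjusted p 0.0503 to 0.0723). LINC00877 fell by 0.57, and its call ended without the second or the third mock library, any IFN-β library, the first R848 library or the second R848 plus B18R library (adjusted p 0.0537 to 0.148). Since the deposited notes do not give the strand setting of the counting, values of antisense transcripts can hold reads of the gene they overlap, and values of paralogs such as the HLA and IFIT genes can depend on the setting for multi-mapped reads.

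The comparison of R848 with mock asked what TLR7 signalling changed, with the interferon that the cells themselves make. R848 raised the interferon response and, beside it, the NF-κB and cytokine response of an activated dendritic cell. IFNB1 itself rose, with the chemokines CCL1 and CCL2, the cytokines IL6, IL23A, LTA and CSF2, and the NF-κB feedback inhibitors NFKBIA, NFKBIZ and TNFAIP3. The lymph node homing receptor CCR7, the maturation markers CD83, CD80 and CD40 and the HLA class II gene HLA-DRA rose. The chemokine receptor CCR2, the ER protein gene DERL3, the growth regulator MYC and the pDC marker BLNK fell.

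IFIT1 rose by 9.47 ± 0.24 (adjusted p = 3.6e-12) and OAS1 by 8.48 ± 0.12 (adjusted p = 3.5e-14), in 3 of 3 libraries. CCL2 (ENSG00000108691) rose by 8.47 ± 0.49 (adjusted p = 1.2e-08) from a mock level of −1.89, CCR7 (ENSG00000126353) by 7.39 ± 0.18 (adjusted p = 2.9e-12) and NFKBIA (ENSG00000100906) by 3.25 ± 0.12 (adjusted p = 9.9e-11). IFNB1 rose by 8.54 ± 1.02 (adjusted p = 1.4e-05) and CCL1 by 8.87. MX2 rose by 12.01, OAS2 by 10.55, IFI6 by 10.39, IFI44 by 10.12, EPSTI1 by 9.86 and XAF1 by 8.96. The mock levels of CCL1 (−4.971), MX2 and IFI44 lay below that of 3 counts in a library, and that of IFNB1 was −3.752 (SD 2.248). The sizes of the changes of these genes are therefore approximate. IFI44L had a count ratio of 11073 (95% interval 3065 to 91437) over mock, where it had 2 counts. IL6 was at least 166.9-fold higher and CD40 at least 152-fold higher than in mock, where neither was counted. MYBPH fell by 4.07 ± 0.13 (adjusted p = 2.9e-11). The change was −5.76 for MDFI, −4.02 for AC119396.1, −3.90 for CCR2, −3.78 for ACP5, −3.75 for C16orf74, −3.65 for SCN9A and −3.43 for DERL3. Further genes raised were LTA (4.80), BIRC3 (4.61), CD83 (4.30), NFKBIZ (4.04), CD80 (3.75), TNFAIP3 (1.70) and TNF (1.18), and MYC fell by 1.50.

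**Figure D2:**
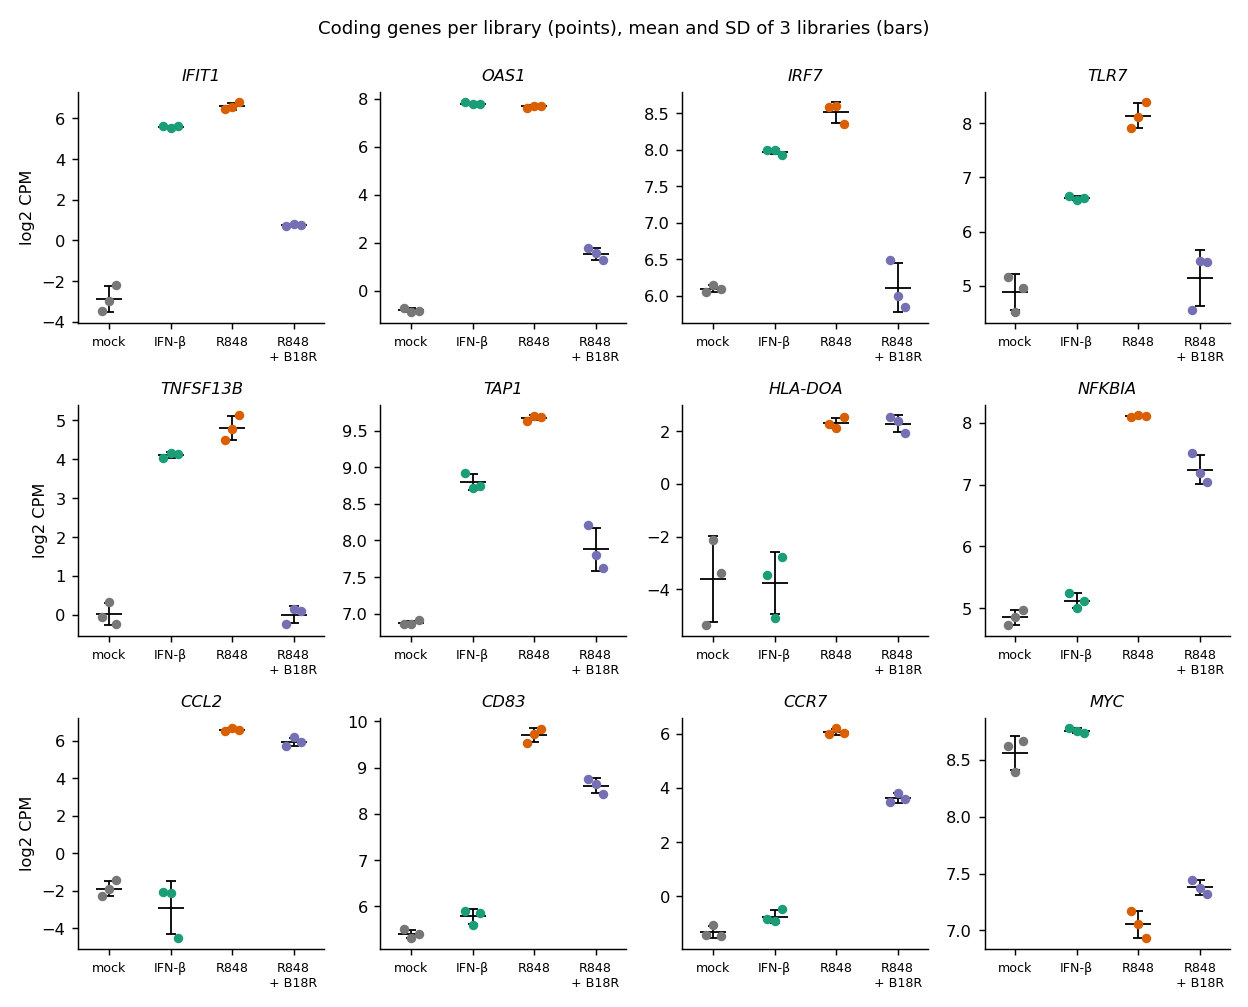
Level (log2 CPM) of 12 protein-coding genes in each library, with the mean and SD of each group of 3 libraries. IFIT1, OAS1, TLR7 and TNFSF13B were high with IFN-β and R848 and lower with R848 plus B18R. CCL2, CD83, CCR7, NFKBIA and HLA-DOA were above mock in both groups with R848. Of these, CCR7, CD83 and NFKBIA were called lower with R848 plus B18R than with R848 (CCR7 at 3.627 against 6.071).

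R848 changed 3556 genes upward and 2998 downward, 1032 and 1117 of them by at least 2-fold, and 7864 genes did not overlap against 10% by chance. Higher genes were 54.3% of the calls, 43.2% with quantile normalization and 24.3% with scaling by library total, which moved the median change of all genes to −0.30 from 0.04. Relative to that shift, the directions of the following lists held except where stated. All 38 ISGs were higher (also over the list alone, median 5.58, camera adjusted p = 2.1e-31), as were 17 of 20 JAK-STAT genes with 1 lower, IFNAR2 (the same over the list alone, camera adjusted p = 3.4e-08). NF-κB targets had 24 of 26 higher and 2 lower, SOD2 and PLAU (the same over the list alone, median 2.42, camera adjusted p = 1.2e-13). Cytokines had 14 of 15 higher and 1 lower, IL18 (the same over the list alone, median 4.78, camera adjusted p = 6.8e-11). Of the 38 fixed cytokine entries 18 were found in the table, and identifiers without a symbol could not be matched to any list. Among such identifiers, ENSG00000006075, ENSG00000129277 and ENSG00000161570 had 4725, 1228 and 543 counts with R848 and 0 in mock. Dendritic cell maturation genes had 12 of 14 higher (the same over the list alone, camera adjusted p = 3.4e-08), and all 15 MHC class II genes were higher (the same over the list alone, camera adjusted p = 4.0e-09). MHC class I genes had 15 of 21 higher (the same over the list alone), and 13 higher and 4 lower with quantile normalization. Their camera adjusted p was 1.2e-06, and 0.136 with an estimated correlation.

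The TLR pathway had 12 of 19 genes higher and 3 lower (14 and 3 over the list alone, camera adjusted p = 0.00271), and 8 higher and 4 lower with scaling by library total. TLR7 rose by 3.27 and MYD88 by 2.24, while TLR3 fell. Cell death regulators had 17 of 21 higher and 1 lower, BCL2 (the same over the list alone, camera adjusted p = 3.5e-06), with BCL2L11 raised by 2.41 and PMAIP1 by 2.13. Of 27 pDC identity genes, 11 were higher and 12 lower (12 and 13 over the list alone, camera adjusted p = 0.124), and 3 higher and 13 lower with quantile normalization. Among them MZB1 (−2.15), BLNK (−2.07), LAMP5 (−1.91) and TCL1A (−0.91) fell, and CD2AP rose by 1.14.

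Among lncRNAs, R848 raised MIR155HG and MIR3142HG, the host transcripts of the inflammatory microRNAs miR-155 and miR-146a, and LUCAT1, LINC-ROR and ITGB2-AS1. LCT-AS1, TMCC1-DT and DANCR fell. LUCAT1 (ENSG00000248323) rose by 3.92 ± 0.21 (adjusted p = 5.1e-09), MIR3142HG (ENSG00000253522) by 3.25 ± 0.15 (adjusted p = 1.0e-09) and MIR155HG (ENSG00000234883) by 2.10 ± 0.23 (adjusted p = 7.6e-06), in 3 of 3 libraries each. LINC01686 rose by 3.40, ITGB2-AS1 by 2.64, ENSG00000258875 by 2.51 and IRF1-AS1 by 1.67. ENSG00000272733 fell by 5.79 ± 0.64 (adjusted p = 6.9e-06), and LCT-AS1 (−2.89), ENSG00000248015 (−2.31) and TMCC1-DT (−2.20) fell too. From the fixed list, MIR3945HG rose by 5.65, LINC00158 by 5.41, MIR22HG by 4.28 and LINC01215 by 3.59, and DANCR fell by 1.03. That list had 15 of 33 higher and 7 lower (16 and 7 over the list alone, camera adjusted p = 0.124), and 11 higher and 13 lower with scaling by library total. In all, 142 lncRNAs were higher and 355 lower.

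**Figure D3:**
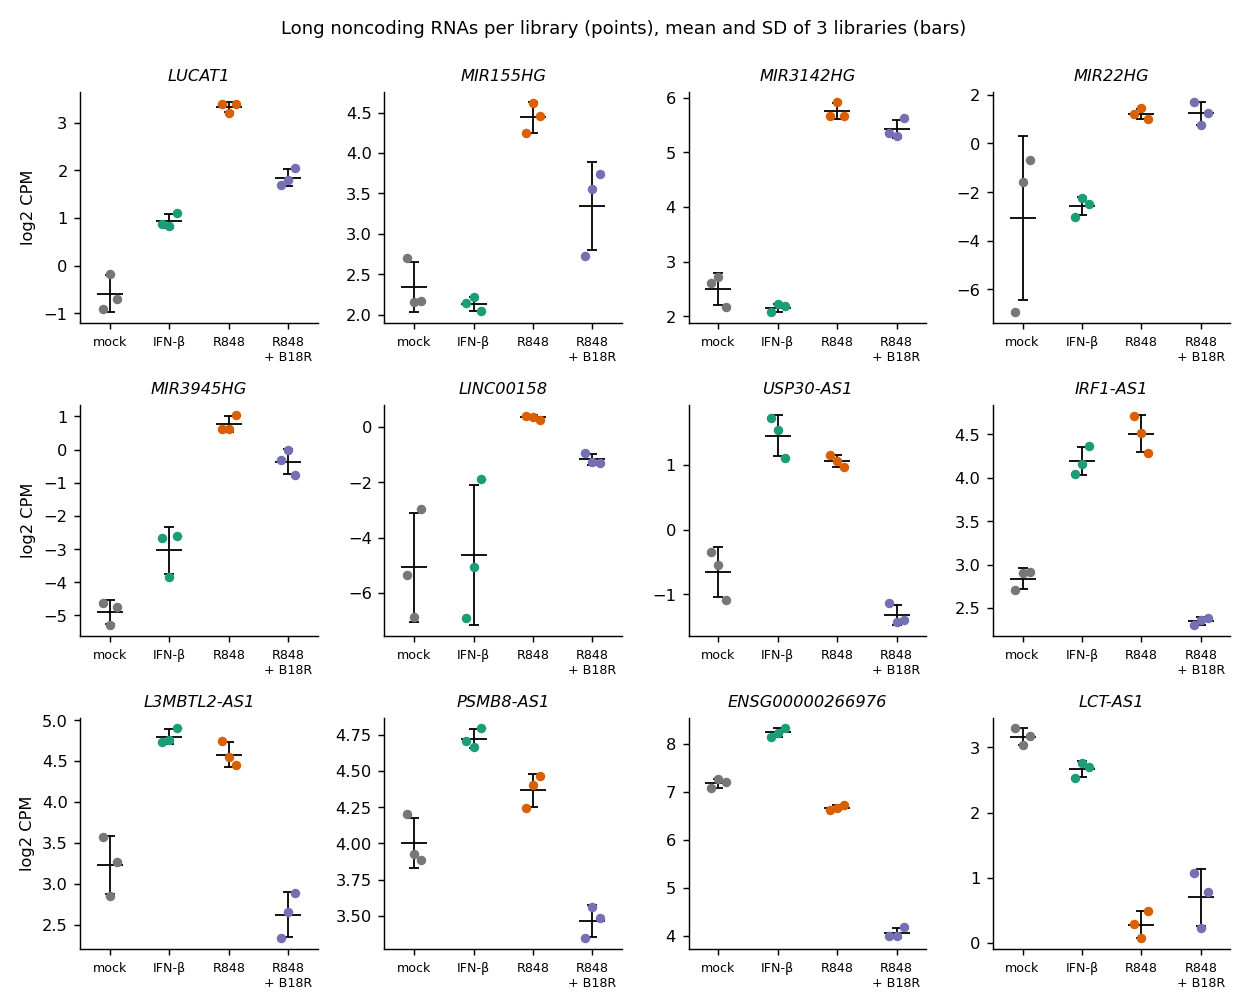
Level (log2 CPM) of 12 lncRNAs in each library, with the mean and SD of each group of 3 libraries. IRF1-AS1, L3MBTL2-AS1 and USP30-AS1 were high with IFN-β and with R848 but not with R848 plus B18R, and MIR3142HG was high in both groups with R848.

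The comparison of R848 plus B18R with mock asked what R848 changed with extracellular type I interferon bound. The cytokine genes CCL1, CCL2 and CSF2, the activation marker CD69, the nuclear receptor NR4A3 and the maturation gene CCR7 stayed far above mock. The BAFF gene TNFSF13B, the ISG IFI27 and the sensor TLR7 were not called against mock. CCL2 rose by 7.82 ± 0.49 (adjusted p = 6.6e-08), CCL1 by 8.45, CDH1 by 7.10, CSF2 by 6.75, IFNB1 by 6.62, CD69 by 6.55, IL32 by 6.32, NR4A3 by 6.06, SGK1 by 5.98, EGR3 by 4.96, CCR7 by 4.94 and IGFBP5 by 4.45. The sizes for CCL1 and IFNB1 are approximate, since their mock levels lay below or near that of 3 counts in a library. IL6 was at least 32.9-fold and CD40 at least 74.9-fold higher than in mock. CCR2 fell by 3.41 ± 0.24 (adjusted p = 1.7e-07), and the change was −3.40 for SCN9A, −3.24 for MYBPH, −2.97 for IGLL1, −2.93 for MDFI, −2.87 for TNNT3, −2.78 for AC119396.1 and −2.77 for ACP5. The change was 0.27 ± 0.22 for TLR7 (adjusted p = 0.37), 0.05 for IFI27 and −0.01 for TNFSF13B.

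In all, 2613 genes were higher and 2097 lower than mock, 546 and 589 of them by at least 2-fold, and 5342 did not overlap against 10% by chance. With the 2 groups alone 1640 were higher and 1248 lower, and with array weights 4521 and 3952. Higher genes were 55.5% of the calls and 26.6% with scaling by library total, which moved the median of all genes to −0.21 from 0.01. Of the ISGs, 24 of 38 were higher and 1, HERC5, lower (25 and 1 over the list alone, median 1.10, camera adjusted p = 5.4e-10). IFI44L had a count ratio of 111 over mock (95% interval 30.4 to 925). JAK-STAT genes had 14 of 20 higher and 1 lower (the same over the list alone, camera adjusted p = 4.3e-06). NF-κB targets had 21 of 26 higher and 3 lower (the same over the list alone, median 1.64, camera adjusted p = 1.5e-14) and cytokines 13 of 15 higher and 1 lower (the same over the list alone, median 3.58, camera adjusted p = 5.4e-12). Maturation genes had 10 of 14 higher (14 over the list alone, camera adjusted p = 3.8e-09) and MHC class II genes 13 of 15 higher (the same over the list alone, camera adjusted p = 2.2e-10). MHC class I genes had 10 of 21 higher and 2 lower (the same over the list alone). Their camera adjusted p was 0.00752, 0.435 with an estimated correlation and 0.0700 without the first R848 plus B18R library.

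The TLR pathway had 8 of 19 genes higher and 4 lower (9 and 4 over the list alone, camera adjusted p = 0.171), and 3 higher and 5 lower with scaling by library total. The pDC identity genes moved downward, 4 of 27 higher and 13 lower (4 and 14 over the list alone, median −0.37, camera adjusted p = 0.000624, and 0.108 with an estimated correlation). The C-type lectin CLEC4C (BDCA-2), a pDC marker, fell by 2.00, and BLNK fell by 2.25. Cell death regulators had 12 of 21 higher and 2 lower (14 and 2 over the list alone, camera adjusted p = 0.00212, and 0.108 with an estimated correlation). Among lncRNAs, MIR3142HG rose by 2.93 ± 0.15 (adjusted p = 6.9e-09), ITGB2-AS1 by 2.48, ENSG00000258875 by 2.04, H1-10-AS1 by 1.65, GP6-AS1 by 1.30, ENSG00000257883 by 1.29 and MIR23AHG by 1.18. ENSG00000269968 rose by 1.07, a call that ended without the first mock library (adjusted p = 0.134) or the first R848 plus B18R library (adjusted p = 0.0824). ENSG00000266976 fell by 3.12 ± 0.09 (adjusted p = 6.3e-11), and ENSG00000272733 (−5.50), LCT-AS1 (−2.47) and LINC01355 (−1.76) fell too. In all, 78 lncRNAs were higher and 275 lower. The known lncRNAs had 11 of 33 higher and 7 lower (11 and 8 over the list alone, camera adjusted p = 0.33), and 10 higher and 11 lower with scaling by library total.

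The comparison of R848 plus B18R with R848 asked which part of the R848 response needed type I interferon outside the cell. B18R lowered every one of the 38 ISGs, among them IFI27, IFI44, MX2, IFI6, OAS1, OAS2 and IFIT1, and with them the interferon-induced TLR7, IRF7, TNFSF13B and TNFSF10. Smaller decreases reached CCR7, CD83 and NFKBIA, whereas HLA-DRA, HLA-DOA, CCL2 and CSF2 were not called. Of the 738 genes that rose, R848 had lowered 634, FAM78A, MB, SPNS2 and GRIN2B among them. IFI27 (ENSG00000165949) fell by 7.70 ± 0.50 (adjusted p = 1.5e-07), OAS1 fell by 6.13 ± 0.12 (adjusted p = 2.5e-12) and IFIT1 fell by 5.83 ± 0.24 (adjusted p = 1.5e-09), in 3 of 3 libraries each. The change was −7.02 for IFI44, −6.85 for MX2, −6.70 for IFI6, −6.60 for IFI44L, −6.34 for OAS2, −4.79 for TNFSF13B, −3.50 for TNFSF10, −3.00 for TLR7, −2.44 for CCR7, −1.09 for CD83 and −0.86 for NFKBIA. IFNB1 itself, with a change of −1.92 ± 1.02 (adjusted p = 0.24), was not called. Its level was 2.866 (SD 0.548) against 4.789 (SD 0.245) with R848. The standard error is shared over the groups, and the SD was 2.248 in mock and 2.113 with IFN-β. CCL2 was at 5.928 (SD 0.227) against 6.575 (SD 0.079) with R848, with an SD of 1.413 with IFN-β. A decrease of either gene with B18R is therefore not excluded. FAM78A (ENSG00000126882) rose by 1.71 ± 0.12 (adjusted p = 3.3e-07), MB by 1.66, SPNS2 by 1.37, ADGRA2 by 1.31, TBC1D10C by 1.29, DBP by 1.25, PHETA1 and GRIN2B by 1.20 each, VIPR1 by 1.12, POLR1G by 1.11 and SLA and SPEG by 1.09 each.

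In all, 738 genes were higher and 1048 lower, 88 and 373 of them by at least 2-fold, and 3913 did not overlap against 10% by chance. The higher count was 368 without the second and 369 without the third R848 library. With sequencing run as a factor 353 were higher, run 1 holding no library with B18R, and with the 2 groups alone 203 were higher and 656 lower. With array weights 4151 were higher and 3847 lower, and with scaling by library total 1792 were higher. Higher genes were 41.3% of the calls, 51.7% with quantile normalization and 69.1% with scaling by library total, which moved the median of all genes to 0.12 from 0.00. The ISGs had a median change of −4.24 (38 lower, also over the list alone, camera adjusted p = 3.3e-68). JAK-STAT genes had 11 of 20 lower and 1 higher (13 and 2 over the list alone, camera adjusted p = 4.5e-08). NF-κB targets had 12 of 26 lower (12 and 1 over the list alone, median −0.32, camera adjusted p = 7.7e-07), cytokines 6 of 15 lower (the same over the list alone, camera adjusted p = 4.9e-05) and maturation genes 8 of 14 lower (8 and 1 over the list alone, camera adjusted p = 1.8e-05). MHC class I genes had 13 of 21 lower (16 over the list alone, camera adjusted p = 1.8e-09, and 0.064 with an estimated correlation), and MHC class II genes 3 of 15 lower and 1 higher (4 and 1 over the list alone, camera adjusted p = 0.071, and 1 lower and 2 higher with scaling by library total). The TLR pathway had 6 of 19 lower (8 over the list alone, camera adjusted p = 0.00298), and cell death regulators 11 of 21 lower (11 and 1 over the list alone, camera adjusted p = 1.2e-06). Of pDC identity genes 7 were lower and 6 higher (8 and 8 over the list alone, camera adjusted p = 0.389).

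Among lncRNAs, B18R lowered the interferon-induced IRF1-AS1, L3MBTL2-AS1 and USP30-AS1, and raised BAIAP2-DT and HCG11. ENSG00000266976 fell by 2.61 ± 0.09 (adjusted p = 3.4e-10) and IRF1-AS1 fell by 2.16 ± 0.14 (adjusted p = 9.3e-08). USP30-AS1 (−2.38), L3MBTL2-AS1 (−1.96), TRMT61A-DT (−1.75), LUCAT1 (−1.48) and MIR155HG (−1.10) fell too. ENSG00000261226 rose by 1.35, BAIAP2-DT by 0.93 ± 0.12 (adjusted p = 0.00011), LINC00877 by 0.71 and HCG11 by 0.53. C10orf95-AS1 (0.60), DDN-AS1 (0.58), SNHG19 (0.53) and PP7080 (0.47) rose too, but each call ended without the third R848 library (adjusted p 0.0809, 0.0909, 0.0807 and 0.0791). The call of PP7080 also ended without the second R848 library (0.0562), that of DDN-AS1 without the second R848 library or the first or the second R848 plus B18R library (0.0621 to 0.0725), and that of SNHG19 without the third mock library, the second IFN-β library, the first or the second R848 library or the first or the third R848 plus B18R library (0.0505 to 0.111). MIR3142HG, with a change of −0.32, was not called (adjusted p = 0.18). In all, 37 lncRNAs were higher and 53 lower. Their total of 90 was 51 without the second and 54 without the third R848 library. The known lncRNAs had 5 of 33 lower (the same over the list alone, camera adjusted p = 0.126).

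The part of the R848 response that B18R lowered was then set against the genes that IFN-β raised on its own. No group was given B18R alone, so effects of B18R other than binding interferon were not tested. Of 3556 genes raised by R848, B18R lowered 916 (25.8%), where independence would give 291, and raised 16. The same R848 libraries stand in both comparisons, so part of the excess can come from them. In 20 simulations without any change the mean overlap was 0, but a mean of 0.1 genes was called higher with R848, so these do not measure the sharing. IFN-β and R848, compared with the same mock libraries, both raised 451 genes, where independence would give 134, and part of this excess can come from the shared mock libraries. Of these 451, B18R lowered 418 (92.7%), among them the ISGs, TLR7 and IRF1-AS1. Of the 3105 raised by R848 but not called higher with IFN-β, B18R lowered 498 (16.0%), among them CCR7 and CD83. The odds ratio was 66.2 (Fisher's exact p = 8.0e-238, genes not being independent). A missing call is not a lack of response, since the simulated IFN-β comparison recovered 19 of 66 genes changed by 0.5 log2 units. CCR7 itself was at −0.753 (SD 0.235) with IFN-β and at −1.317 (SD 0.233) in mock. Among the 1032 genes raised at least 2-fold by R848, B18R lowered 556 (53.9%), 310 of the 319 that IFN-β raised and 246 of the other 713. Among 142 lncRNAs raised by R848, IFN-β raised 27, of which B18R lowered 24, and of the other 115 it lowered 16. Compared with mock, 74 of the 142 were still higher with R848 plus B18R.

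For the genes raised at least 2-fold by R848, the median retained share of the log2 response was 0.622 (quartiles 0.308 and 0.846), 0.272 for genes that IFN-β raised and 0.753 for the others. The median retained share was 0.222 over 37 ISGs, 0.403 over 12 JAK-STAT genes, 0.570 over 12 MHC class I genes, 0.678 over 12 maturation genes, 0.848 over 22 NF-κB targets, 0.880 over 14 cytokines and 0.923 over 10 MHC class II genes. A share of a log2 change between 0 and 1 exceeds the share of the added RNA that remains. On the linear scale the median share over all tested ISGs was 1.78%. Linear shares of the other lists were not computed, so this value cannot be set against their log2 shares. The R848 libraries both select the genes and form the divisor, which can pull the retained shares below 1. Without genes that had 3 or fewer counts in mock, the median log2 share was 0.215 for ISGs, 0.881 for cytokines and 0.669 for maturation genes. The cytokines were not uniform, since TNFSF13B retained −0.003 of its response. Of the 2998 genes lowered by R848, B18R raised 634 (21.2%), where independence would give 173, and part of this excess can come from the shared R848 libraries.

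**Figure D4:**
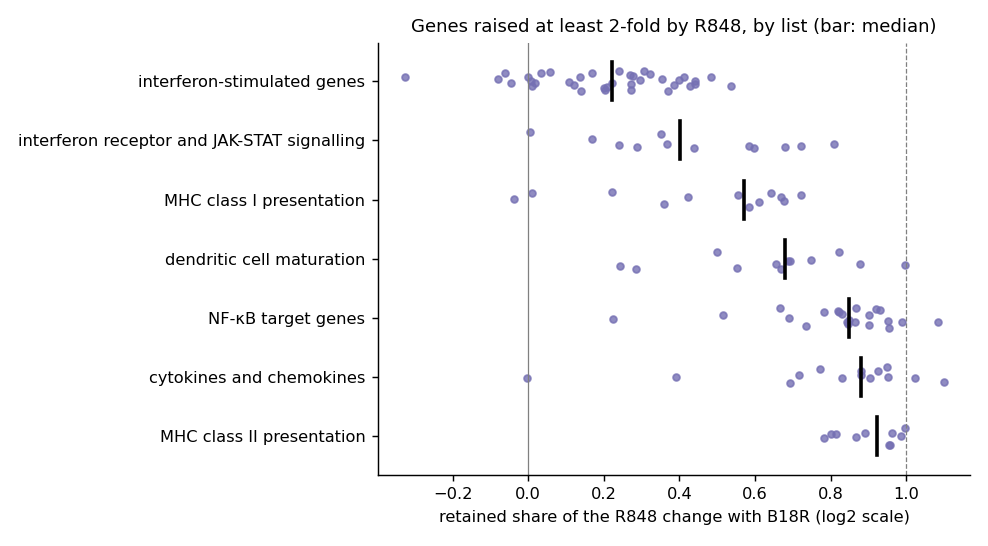
Retained share of the log2 response to R848 with B18R, for genes raised at least 2-fold by R848 in 7 fixed lists; points are genes and bars medians. The median was 0.222 for interferon-stimulated genes and 0.923 for MHC class II genes. On the linear scale the median share over all tested interferon-stimulated genes was 1.78%, and linear shares of the other lists were not computed.

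The log2 change with IFN-β against mock and the change with R848 plus B18R against R848 share no library. Across the 6593 genes called with IFN-β or R848, with genes not being independent replicates, they had a Pearson r of −0.810 and a Spearman rho of −0.650. Over all 12801 genes the Spearman rho was −0.473 and r was −0.739. Simulations without any change gave 5.34e-05, but they drew noise separately for each gene and library, so a value near 0 was set in advance. They hold no deviations shared between libraries, such as those of the second mock and the first R848 plus B18R library (correlation 0.4434, mitochondrial genes left out). These libraries enter the IFN-β and B18R changes with opposite signs and can add to a negative r. Genes such as OAS1 and IFIT1 lay at one end of the relation. CCR7 and NFKBIA fell with B18R with no called change under IFN-β, although the mean level of CCR7 was −0.753 with IFN-β against −1.317 in mock. The IFN-β and R848 changes against the same mock libraries had r = 0.580, where shared mock libraries alone gave 0.498. Their covariance was 0.295, of which 0.0219 came from the shared libraries. The R848 minus IFN-β change and the R848 plus B18R minus mock change, with no library in common, had r = 0.887.

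**Figure D5:**
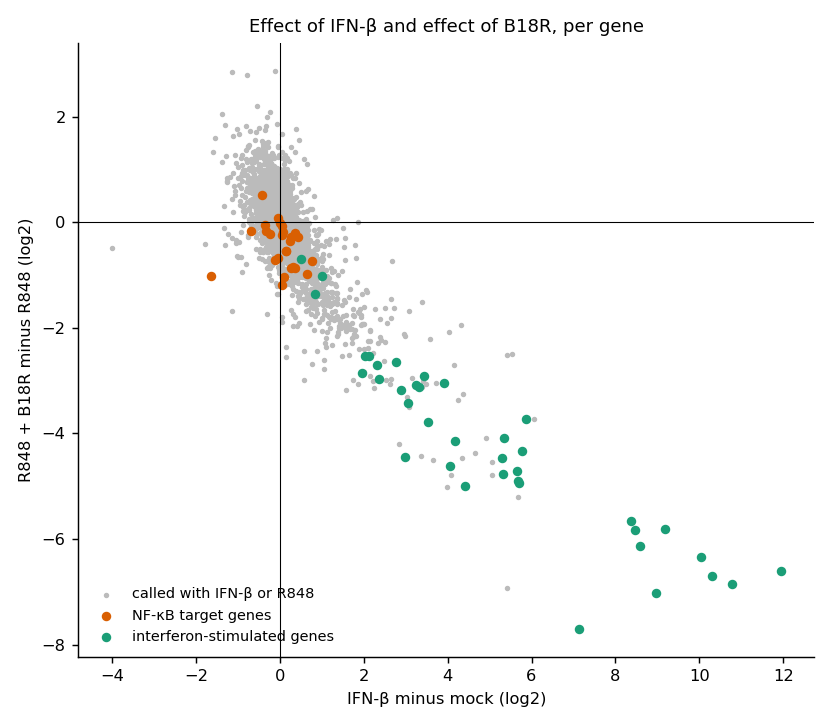
Change with IFN-β against mock (horizontal, log2) and with R848 plus B18R against R848 (vertical, log2) for 6593 genes called with IFN-β or R848, with interferon-stimulated genes and NF-κB targets coloured. Of the 481 genes raised by IFN-β, B18R lowered 436 (90.6%), and r was −0.810.

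The comparison of R848 with IFN-β asked which changes were particular to TLR7 signalling. R848 exceeded IFN-β in the chemokines CCL1 and CCL2, the survival gene BCL2A1, the growth factor gene CSF2, CCR7 and IFNB1, and also in the ISG IFIT2 and in TNFSF10, while OAS1, IFI6 and IFI27 were not called. CCR2, ACP5, IGLL1 and SCN9A were lower with R848. CCR7 was higher by 6.83 ± 0.18 (adjusted p = 1.6e-11), CCL2 by 9.48, BCL2A1 by 8.17, IFNB1 by 7.82, CDH1 by 7.19, CSF2 by 7.15, IL32 by 6.98, SGK1 by 6.90, NR4A3 by 6.69, CD69 by 6.38 and EGR3 by 5.67. BCL2A1 was at −4.696 (SD 1.922) with IFN-β, below the value of 3 counts in a library, so the size of its change is approximate. CCL1 had a count ratio of 2527 (95% interval 453 to 99830) and CD40 of 206 (56.6 to 1705), and IL6 was at least 150-fold higher. IFIT2 was higher by 2.66 ± 0.12 (adjusted p = 2.4e-09) and OAS1 differed by −0.12 ± 0.12 (adjusted p = 0.46). MYBPH was lower, at −3.86 ± 0.13 (adjusted p = 1.5e-10), as were CCR2 (−3.60), ACP5 (−3.49), AC119396.1 (−3.42), IGLL1 (−3.36), SCN9A (−3.15), OCA2 (−3.13) and COL9A3 (−3.10).

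In all, 3177 genes were higher and 2655 lower with R848 than with IFN-β, 684 and 928 of them by at least 2-fold, and 8536 did not overlap against 10% by chance. With array weights 5291 were higher and 4429 lower. Higher genes were 54.5% of the calls and 25.2% with scaling by library total, which moved the median of all genes to −0.23 from 0.05. ISGs had 21 of 38 higher (22 over the list alone, median 0.63, camera adjusted p = 1.2e-05), and 11 higher and 1 lower with quantile normalization. JAK-STAT genes had 16 of 20 higher and 1 lower (the same over the list alone, camera adjusted p = 5.5e-06), NF-κB targets 23 of 26 higher and 1 lower (the same over the list alone, median 2.20, camera adjusted p = 1.4e-15) and cytokines 14 of 15 higher and 1 lower (the same over the list alone, camera adjusted p = 1.9e-11). The counts over the list alone were the same for maturation genes, with 12 of 14 higher (camera adjusted p = 1.6e-09), MHC class II genes, with 13 of 15 higher (camera adjusted p = 1.6e-09) and cell death regulators, with 15 of 21 higher and 1 lower (camera adjusted p = 8.9e-05). MHC class I genes had 10 of 21 higher and 1 lower (the same over the list alone, median 0.25, and −0.02 with scaling by library total). Their camera adjusted p was 0.0127, and 0.43 with an estimated correlation. The TLR pathway had 10 of 19 higher and 3 lower (13 and 3 over the list alone, camera adjusted p = 0.0156). Of pDC identity genes 6 were higher and 13 lower (6 and 14 over the list alone, camera adjusted p = 0.0144, and 0.228 with an estimated correlation).

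Among lncRNAs, LINC-ROR, MIR3142HG, ITGB2-AS1, LUCAT1 and MIR155HG were higher with R848 than with IFN-β, while IRF1-AS1 and L3MBTL2-AS1 were not called. MIR3142HG was higher by 3.59 ± 0.15 (adjusted p = 7.5e-10), LINC-ROR by 4.10, LINC01686 by 3.20, ITGB2-AS1 by 2.96, ENSG00000258875 by 2.73, LUCAT1 by 2.39, MIR155HG by 2.30 and GP6-AS1 by 1.48. ENSG00000272733 was lower, at −5.42 ± 0.64 (adjusted p = 1.9e-05), as were LCT-AS1 (−2.38), TMCC1-DT (−2.26) and ENSG00000224945 (−1.86). In all, 99 lncRNAs were higher and 338 lower. The known lncRNAs had 12 of 33 higher and 8 lower (the same over the list alone, camera adjusted p = 0.232).

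The lncRNAs were called less often than protein-coding genes in each comparison: 3.46% against 4.85% with IFN-β (Fisher's exact p = 0.0409), 46.4% against 53.5% with R848 (Fisher's exact p = 1.22e-05), 33.0% against 38.7% with R848 plus B18R against mock (Fisher's exact p = 0.000277), 8.41% against 15.3% with R848 plus B18R against R848 (Fisher's exact p = 1.02e-10) and 40.8% against 47.6% for R848 against IFN-β (Fisher's exact p = 2.51e-05). These Fisher tests treat genes as independent, which they are not, and the comparisons share libraries. Protein-coding genes matched in level to the lncRNAs were called at 4.73%, 56.8%, 38.9%, 14.8% and 50.1%. The median standard error of a log2 change was 0.271 for lncRNAs and 0.141 for protein-coding genes. With a 2-fold minimum, lncRNAs were instead called more often than all genes tested in each comparison. In the same order, 25, 84, 46, 12 and 59 of 1070 lncRNAs were higher and 3, 202, 114, 34 and 179 lower. Of all 12801 genes, 223, 1032, 546, 88 and 684 were higher and 11, 1117, 589, 373 and 928 lower.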

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

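The tests of depth, sequencing run and RNA composition for the first R848 plus B18R library, of R848 RNA mixed into other libraries, and of reads counted on the wrong strand were chosen after the results they weigh had been seen; the tests of unbound interferon and of induction without interferon were not. IFN-β and R848 moved some genes in opposite directions. The butyrophilins BTN3A1, BTN3A2 and BTN3A3, surface proteins through which phosphoantigens activate γδ T cells, rose with IFN-β and fell with R848, as did TENM4 and SERHL2. IL1B, the lectin gene CLEC10A, the connexin gene GJB2, and MYEOV, LFNG, SAMD14, HECW1 and TRIM13 fell with IFN-β and rose with R848. These genes were singled out because each was called both ways, by at least 1.5-fold, and the R848 and IFN-β libraries differed in a direct test.

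R848 minus IFN-β was −1.42 for BTN3A1, −1.64 for BTN3A2, −1.59 for BTN3A3, −1.92 for TENM4 and −2.53 for SERHL2, all in log2 units. It was 2.93 for IL1B, 1.79 for CLEC10A, 4.07 for GJB2, 4.04 for MYEOV, 2.47 for LFNG, 2.33 for SAMD14, 2.24 for HECW1 and 1.50 for TRIM13. Against mock, BTN3A2 rose by 0.59 ± 0.10 with IFN-β (adjusted p = 0.0033) and fell by 1.05 ± 0.10 with R848 (adjusted p = 2.6e-06). Without a library, 8 of the IFN-β calls ended. These were BTN3A3 without the second IFN-β library (adjusted p = 0.0504), TENM4 without the first mock or the third IFN-β library (0.0503 and 0.0505), MYEOV without the first mock or the second IFN-β library (0.0501 and 0.059), and GJB2 without the first or the third mock or the second or the third IFN-β library (0.0572 to 0.124). SAMD14 was not called without the second or the third mock, the first or the third IFN-β or the second R848 library (0.0508 to 0.161), and HECW1 without the second or the third mock, any IFN-β, the first or the second R848 or the second R848 plus B18R library (0.0528 to 0.187). LFNG was called only without the first mock or the first R848 plus B18R library, and CLEC10A only without the latter (otherwise 0.0536 to 0.217 and 0.052 to 0.162). In all, 8 genes were raised by IFN-β and lowered by R848 and 22 the other way.

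Some genes of the fixed lists that lay under the level filter had counts in treated libraries above those of mock, and others below. With R848, over 3 libraries, the IL-27 subunit genes EBI3 and IL27 had 53 and 51 counts, the receptor gene SLAMF1 155, the ISGs PARP12 and RTP4 77 and 60, VCAN 56 and TLR8 41. MX1 had 55 counts over the 3 IFN-β libraries, a count that may depend on the unknown setting for multi-mapped reads, which was not tested. In mock, SLAMF1, RTP4, VCAN and TLR8 had 0 counts, EBI3, IL27 and MX1 had 1 and PARP12 had 3. The pDC identity genes PTCRA and PACSIN1 went the other way, with 29, 31 and 18 and 45, 28 and 83 counts in the mock libraries and 0, 6 and 1 and 0, 19 and 8 in the R848 libraries. They had 8, 0 and 4 and 24, 8 and 18 counts in the IFN-β libraries, so low counts were not particular to R848. These levels were not tested.

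The first R848 plus B18R library lay apart from the other two of its group, at 0.585 log2 units against at most 0.398 for any other library. Its depth of 68.33 M counts lay between those of the other two, 53.94 and 74.52, so a lower depth did not set it apart. It shared a sequencing run with the third library of its group, yet lay 0.624 log2 units from it, while the second and the third, of different runs, lay 0.271 apart. The difference of 0.3527, against an SD of 0.0794 among the distances within the other groups, argues against the run as the whole cause. Its deviations across genes had a mean correlation of 0.0772 with those of the libraries of its run in other groups (−0.05735 with the third mock library and 0.2118 with the first R848 library). Its deviations correlated at 0.4434 with those of the second mock library, with mitochondrial genes left out, where the next highest pair had 0.4151 (the first mock and the third R848 library) and its own with the first mock library was −0.4226. A difference in RNA composition shared with the second mock library may therefore contribute, and no biological explanation was tested.

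With R848 plus B18R, 24 of 38 ISGs, IFIT2 and IFIH1 among them, stayed above mock. R848 RNA mixed into these libraries would give every ISG the same linear share of its R848 increase, but the share was −11.1% for HERC5, 1.01% for IFI44L, 10.9% for IFIH1 and 11.2% for IFIT2 (11.3% for CNP, with a standard error of 16.8%), and its SD across genes was 7.246 times its median standard error, which argues against mixing as the whole cause. Interferon not bound by B18R remains open, since the ISG changes correlated with those under IFN-β, with separate mock libraries, at Spearman 0.7111 to 0.8243 over 3 splits of the mock group (permutation p = 1e-05, the smallest that 100000 permutations can give). Induction by R848 without type I interferon remains open as well, since the same changes correlated with R848 minus IFN-β at 0.4098 (permutation p = 0.01152, both tests two-sided). Other inducers of ISGs could give a correlation with the IFN-β changes too, so that test does not single out unbound type I interferon. Both explanations may act, others were not tested, and the design has no group that separates them.

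Antisense lncRNAs such as IRF1-AS1 moved with the gene they are named for, which reads of that gene counted on the wrong strand could produce. Over 200 antisense pairs the Spearman correlation of R848 changes was 0.258, and over 119 divergent pairs 0.421. Pairs were taken from the symbols, and whether their members overlap was not checked by coordinates. The difference of −0.1628 (95% bootstrap interval −0.3703 to 0.06552, 2000 resamples) includes 0, so strand errors and shared regulation cannot be told apart for the antisense group. Of 61 antisense pairs with both members called, 37 went the same way and 24 opposite ways. RNF213-AS1 fell by 1.33 ± 0.23 with IFN-β (adjusted p = 0.0034) while RNF213 rose by 2.14 ± 0.11 (adjusted p = 1.8e-08), so not every antisense value follows its named gene.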

How the results depend on the processing

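The voom precision weights, the scaling by library total and the omission of both libraries of low mitochondrial share (the second mock and the first R848 plus B18R library) were chosen after seeing the data. Values are given in the order IFN-β, R848 and R848 plus B18R against mock, R848 plus B18R against R848, and R848 against IFN-β. Counts of genes kept within 1.5 times their values in the report with median centring, without the intensity trend and with voom weights. Without a filter, 786 lncRNAs were called with R848, and the correlation of the IFN-β and B18R changes was −0.75. With the stricter filter, 22, 226, 173, 57 and 209 lncRNAs were called and the correlation was −0.84, since fewer genes were tested. Quantile normalization gave 161 genes lower with IFN-β. With array weights, whose estimation stopped before it converged, IFN-β gave 1209 higher, 1121 lower and 127 lncRNAs, R848 plus B18R against mock 4521, 3952 and 631, R848 plus B18R against R848 4151, 3847 and 632, and R848 against IFN-β 5291, 4429 and 734, while B18R lowered 2655 genes raised by R848 and the correlation was −0.78; the cause was not tested. With the 2 groups alone in the fit, and so fewer libraries for the spread, 201 genes were lower with IFN-β, 1640 higher, 1248 lower and 216 lncRNAs were called with R848 plus B18R against mock, and 203, 656 and 40 against R848. With replicate number as a block, 52 genes were lower with IFN-β; the numbers do not mark a known pairing, and correlations of like-numbered libraries' deviations ran from −0.511 to 0.245. With sequencing run as a factor, 353 genes were higher in R848 plus B18R than in R848 and 54 lncRNAs were called. At an adjusted p under 0.01, 26 genes were lower and 22 lncRNAs called with IFN-β, 1732 higher, 1224 lower and 195 lncRNAs with R848 plus B18R against mock, 274, 655 and 36 against R848, and 273 lncRNAs in R848 against IFN-β, where 7 lists were called; B18R lowered 575 genes raised by R848 and the correlation was −0.83. With a 2-fold minimum, IFN-β gave 223 and 11, R848 1032, 1117 and 286 lncRNAs, R848 plus B18R against mock 546, 589 and 160, against R848 88, 373 and 46, and R848 against IFN-β 684, 928 and 238, with 311 genes lowered and a correlation of −0.84. Scaling by library total gave 179 genes lower with IFN-β, 1818 higher and 5665 lower with R848, 1437 and 3973 with R848 plus B18R against mock, 1792 higher against R848, and 1594 and 4736 for R848 against IFN-β; the shift of all genes given in the report moves them. Without both libraries of low mitochondrial share IFN-β gave 739 higher, 367 lower and 60 lncRNAs, against 771, 294 and 57 without the first R848 plus B18R library alone, which enters that comparison by the shared spread. Adjusted over lncRNAs alone, 59 were called in R848 plus B18R against R848. With an estimated correlation 3, 6 and 7 lists were called with IFN-β, with R848 plus B18R against mock and against R848, and with fry 16 with R848 and 17 for R848 against IFN-β. A retained share under 0.5 held for 406 genes raised by R848. Leaving out a library at a time gave 340 to 771 genes higher and 28 to 294 lower with IFN-β and 21 to 57 lncRNAs, 368 to 948 genes higher and 51 to 97 lncRNAs in R848 plus B18R against R848, and a correlation of −0.84 to −0.78. The adjusted p of the mitochondrial list in R848 plus B18R against R848 ran from 0.00289 to 0.951, and its direction turned without the first R848 plus B18R library (0.951). With scaling by library total the change of FCGR2B with R848 turned to −0.0390 (adjusted p = 0.775).

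In limma on the 6 libraries of each comparison alone, the real split gave 811, 6954, 2888, 859 and 7838 genes and the highest other split 0 in each, with 1418, 505, 1623, 1011 and 228 genes at most at an unadjusted p under 0.05. The 6 libraries make 10 splits, of which 1 in each comparison reached the real count, so the share cannot be under 0.05. Part of the 916 genes both raised by R848 and lowered by B18R may come from the R848 libraries that both comparisons share, and 811 were lowered with replicate number as a block.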

Other observations

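The test of basal interferon below was chosen after the result it weighs had been seen. Single genes of metabolism and growth changed with R848, although of their 5 lists only glycolysis was called. The glucose transporter gene SLC2A3, the glycolytic genes PFKFB3 and PGAM1 and the stress factors ATF3 and PPP1R15A rose, the cyclin gene CCND3 rose, and MYC and E2F2 fell. With R848 against mock PGAM1 rose by 1.14, SLC2A3 and PFKFB3 by 1.12 each, ATF3 by 3.14, PPP1R15A by 2.16 and CCND3 by 0.78, and E2F2 fell by 0.91. Against R848 alone, the change with B18R was −1.05 for CCND3.

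As lists, these genes had medians of −0.01 to 0.30 with R848, and of −0.35 to −0.04 with scaling by library total. With R848 against mock, cell cycle genes had 13 of 38 higher and 3 lower, but 5 and 18 with scaling by library total; ribosome biogenesis and MYC targets 7 of 25 and 6, but 1 and 14; cholesterol genes 6 of 24 and 5, but 3 and 11; ER stress genes 8 of 23 and 1, but 3 and 8; glycolysis genes 9 of 19 and 1, but 5 and 4. Their camera adjusted p-values were 0.273, 0.557, 0.692, 0.105 and 0.0353, the last of them 0.624 with an estimated correlation, 0.883 with quantile normalization, 0.086 with scaling by library total, 0.0681 without the first mock library and 0.0735 without the first R848 library. Over the list alone the counts were the same, except that no ER stress gene was lower. With IFN-β, 2, 0, 1, 1 and 2 genes of these lists were higher (camera adjusted p 0.0648, 0.64, 0.0648, 0.705 and 0.12), with 1 ribosome gene at an unadjusted p under 0.05 in limma, and SLC2A3 was the single gene lower, a call that ended without any mock or IFN-β library, the second R848 library or the second R848 plus B18R library (adjusted p 0.0506 to 0.151).

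With R848 plus B18R against mock, 5, 6, 5, 9 and 10 genes of the same lists were higher and 6, 3, 4, 1 and 2 lower, and 2, 3, 2, 6 and 4 higher and 17, 8, 6, 4 and 3 lower with scaling by library total. The camera adjusted p-values were 0.579, 0.296, 0.574, 0.0124 and 0.00919. The ER stress and glycolysis lists had 0.421 and 0.555 with an estimated correlation and 0.0714 and 0.115 without the first R848 plus B18R library. Against R848, cell cycle genes such as CCND3 moved downward (3 of 38 lower, camera adjusted p = 0.00385, 0.318 with an estimated correlation and 0.0514 without the third R848 plus B18R library), although with quantile normalization their median was 0.02. Ribosome genes moved upward (2 of 25 higher, camera adjusted p = 0.00298, and 0.16 with an estimated correlation), and the cholesterol, ER stress and glycolysis lists were not called (0.942, 0.996 and 0.753). For R848 against IFN-β none of these lists was called (0.702, 0.365, 0.164, 0.0501 and 0.123).

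Markers of other cells were mostly absent from the tested genes. PAX5, a B cell factor, rose by 2.22 ± 0.09 with IFN-β (adjusted p = 6.7e-10) and by 2.80 with R848, and fell by 3.00 with B18R. With IFN-β, 3 of 5 monocyte and conventional dendritic cell markers fell, LYZ and CD1C among them (4 over the list alone, median −0.75, camera adjusted p = 0.00019, and 0.0726 with an estimated correlation). Against R848, B18R raised 3 of the 5, LYZ, CD1C and CLEC10A (4 higher and 1 lower over the list alone, camera adjusted p = 0.0108, and 0.16 with an estimated correlation). In the comparisons of R848 and of R848 plus B18R with mock and of R848 with IFN-β this list was not called (0.446, 0.877 and 0.596). Of 23 hepatocyte and epithelial markers 3 were in the table, against 32 of 34 pDC identity genes. The 2 tested were general epithelial genes, CDH1, which R848 raised by 7.54, and KRT8, which fell by 1.60. APOA1, under the filter, had 10, 16 and 12 counts in the mock libraries. Of 3 T and NK cell markers, 1 was higher and 2 lower with R848, and of 3 B cell markers 1 was higher and 1 lower. Of the interferon genes, IFNB1 was tested. IFNL1, under the filter, had 36, 40 and 48 counts in the R848 libraries against 0, 0 and 4 in mock. It had 24, 12 and 9 counts with R848 plus B18R and 5, 3 and 15 with IFN-β.

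Mitochondrially encoded genes had a median of 1.22 in IFN-β against mock (camera adjusted p = 0.000257, and 0.497 with an estimated correlation) with 0 of 13 called by limma and 3 at an unadjusted p under 0.05. In R848 plus B18R against R848 the median was −1.01 (camera adjusted p = 0.042, and 0.64 with an estimated correlation), and the call ended without the first or second R848 library (0.104 and 0.105) and turned direction without the first R848 plus B18R library (0.951). In the other comparisons they were not called (0.077, 0.533 and 0.947). Structured RNAs such as RMRP were not called with IFN-β, R848 or R848 plus B18R against mock (0.139, 0.124 and 0.921). They were lower in R848 plus B18R than in R848 (2 of 7 lower, camera adjusted p = 0.0162, 0.134 with an estimated correlation and 0.101 without the third R848 plus B18R library) and higher in R848 than in IFN-β (6 of 7 higher, camera adjusted p = 0.0207, and 0.144 with an estimated correlation).

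Some genes raised by IFN-β lay below mock with R848 plus B18R: the kinase gene MAP2K6, the chemokine receptor gene CCR1, the Fc receptor gene FCGR2B and CD38. CCR1 rose by 2.84 ± 0.21 with IFN-β (adjusted p = 8.1e-07) and by 1.89 with R848, and was at −2.30 ± 0.21 with R848 plus B18R (adjusted p = 2.9e-06). MAP2K6 was at −2.32, FCGR2B at −1.38 and CD38 at −1.06. Several lncRNAs raised by IFN-β were called below mock as well. These included TRMT61A-DT (−1.16), NRSN2-AS1 (−0.96), AP1G2-AS1 and L3MBTL2-AS1 (−0.61 each), PSMB8-AS1 (−0.54) and IRF1-AS1 (−0.49). A candidate explanation is type I interferon present in mock cells and bound by B18R. Among genes that R848 did not lower, 59 of 473 raised by IFN-β (12.5%) and 298 of 9330 others (3.19%) were below mock (odds ratio 4.318, 95% interval 3.154 to 5.836, Fisher's exact p = 2.663e-17, genes not being independent). Leaving out genes lowered by R848 removes mostly others that lie below mock, so this ratio was largely set by the choice of genes. Over all genes there was no excess: 67 of 481 raised by IFN-β (13.9%) and 2030 of 12320 others (16.5%) were below mock (odds ratio 0.820, 95% interval 0.621 to 1.07, Fisher's exact p = 0.149), so the explanation stays open. Of the 481, 215 were above mock. With no group given B18R alone, repression by R848 that the induced interferon otherwise outweighs stays open as well.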
